A study of Mus musculus with 13 samples.

How the data were processed

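Gene expression was measured with Affymetrix MOE430 arrays, on which a gene is represented by one or more sets of short oligonucleotide probes. The 13 arrays hold RNA from the bladder (3 arrays), the urogenital sinus (4 arrays) and the urethra (3 arrays) of embryonic day 14 mice, and a reference RNA from whole newborn mice (3 arrays). Per the labels, RNA was isolated from microdissected tissue, amplified in 2 rounds, labelled with biotin and hybridized. The region samples were not pooled. The labels do not say whether arrays of different regions came from separate embryos, so p-values measure the spread between these samples.

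The authors deposited 1 table of linear signal intensity for 45101 probe sets. The submitters' processing notes name GCOS, the Affymetrix array software, without a version. The steps between the scans and the table are not given in the sources used here. The deposited intensity values had a 2% trimmed mean of 1500 on every array, with a largest difference between arrays of 0.000137%, so the table was used as it stands. This scaling fixes the trimmed mean and not the median, and the median intensity ranged from 142 to 455 across the 13 arrays. Detection calls were not analysed here. Amplification in 2 rounds shortens transcripts towards their 3' end, and probe sets that lie far from that end lose signal by an amount that differs between arrays.

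Intensities were floored at the 20th percentile of the table (50.23, or 5.65 on the log2 scale) and log2 transformed. The 64 control probe sets were set aside. Of the remaining 45037 probe sets, 34945 carried 1 gene symbol, 932 carried several and 9160 carried none. By Entrez identifier, 34741 of the single symbols matched the RefSeq gene table for the mouse assembly GRCm38.p6, 204 were kept as in the platform annotation, and 0 changed. Probe sets were kept when at least 3 arrays exceeded the 40th percentile (an intensity of 167.76), which left 33125. The kept probe set with the highest mean stood for each gene, and 15019 genes were tested. No genome build is stated for the probe sets, so no coordinates are given. Probe sets whose suffix marks probes shared between transcripts can also bind related genes; among the named genes these stood for Gbp2, Hdc, Acta2, Msx1, Aurkb, Wt1, Colec11, Pcdh8, Upk3b, Krt14, Cldn3, Hbb-y, Tbx3, Casq2 and Slc4a1.

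Models were fitted with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend), with p-values two-sided and adjusted by the Benjamini-Hochberg method over the genes tested. A gene was called at an adjusted p under 0.05. The 10 region arrays shared 1 fit with the region means as its terms, with 7 residual degrees of freedom and 2.83 prior degrees of freedom. The reference arrays repeat 1 kind of pooled RNA, so their mean entered as 1 sample, which is assumed to vary like the region samples. Theiler stage 22 was compared with stage 21 with region as a covariate.

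In all, 27 gene lists with 437 genes were fixed, of which 404 had a named probe set and 383 were tested. Each list was described by its called members, by its members called when p was adjusted over the list alone, and by limma's camera, a test of whether a list moves relative to the other genes. Camera used its preset correlation of 0.01 between genes, with adjustment over the 27 lists of a comparison, and was repeated with an estimated correlation. Between regions, the genes named are Actg2, then up to 10 in each direction with the largest change among called genes whose groups do not overlap, then up to 4 called members of each list with the smallest adjusted p, or the member with the smallest p of a list without called members where an example was needed. Against the reference and between stages the same rule took 5 in each direction. The design, the tests, the lists, this rule and the alternative settings, except those named as added, were chosen before the data were examined. A fold against a group with every array under the filter level of 167.76 is given as a lower bound against that level, as a stand-in for a detection limit, and written "at least".

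The alternatives covered quantile normalization, centring on array medians, other floors and filters, other ways to combine probe sets, other limma settings (array weights, robust eBayes, no intensity trend), the arrays in the fit, Theiler stage as a covariate, each array left out in turn, and blocks for the number in the sample title or for the style of the title (random blocks through duplicateCorrelation, with statmod 1.5.0). The titles are written in 3 styles. The first style holds 2 bladder, 3 sinus and 1 reference array, another holds 1 bladder, 1 sinus and 1 reference array, and the remaining style holds the 3 urethra arrays and 1 reference array. The labels do not say whether styles mark batches. As a fixed block, title style was fitted over all 13 arrays, so that the reference arrays link the styles. The fits were also tested on simulated data with 15019 genes of which 200 were changed. At a log2 change of 1, 10% of the changed genes were called for bladder against urogenital sinus, 6% for urethra against urogenital sinus and 10% for bladder against urethra; at a log2 change of 3 these shares were 92%, 90% and 90%. For the regions against the reference, 0% were called at a log2 change of 1 and 62% at 3. Between 0% and 5% of the simulated calls were false in the 5 comparisons. The simulated genes varied independently of one another, each with the same spread in every group. Real genes can move together across arrays, so these shares need not hold for the real data. The number of arrays limits the precision, and an array gives signal over background and not a count of molecules.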

Results

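The bladder, the urogenital sinus and the urethra are neighbouring regions of the lower urinary tract of the mouse embryo. The samples came from FVB/N embryos at embryonic day 14 that carried a transgene in which the promoter of Actg2, the gene for smooth muscle gamma-actin, drives the green fluorescent protein EGFP. Fluorescence guided the dissection: bladder and urethra were taken as fluorescent regions, and the urogenital sinus as the dark region between them. Total RNA was measured on 3 bladder arrays (replicates 2, 6 and 8), 4 urogenital sinus arrays (1, 2, 6 and 7) and 3 urethra arrays (1, 2 and 6). Another 3 arrays held a reference RNA pooled from whole mice at postnatal day 1, from 4 males and 4 females, which serves as a common standard. Replicates 1 and 2 were at Theiler stage 21 and replicates 6, 7 and 8 at stage 22. The comparisons ask which genes differ between the 3 regions, between the regions and the newborn standard, and between the 2 stages. Values are log2 intensities, differences are log2 fold changes with their standard error (SE), and p-values are limma adjusted p-values unless named otherwise.

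The arrays differed in measures of signal, RNA length and blood content, of which spike-in signal and median intensity partly followed region. Median intensity lay between 142 and 389 on the 10 region arrays. It was 142 to 238 on the bladder arrays, 259 to 389 on the urogenital sinus arrays and 221 to 378 on the urethra arrays. Every bladder array thus lay under every sinus array in median intensity. The share of probe sets above the filter level was likewise 47.1% to 56.7% in the bladder and 57.7% to 67.0% in the sinus. Hbb-bh1, an embryonic globin of primitive red cells, reached 15.04 on urogenital sinus replicate 1 and 14.51 on urethra replicate 1, against 7.41 to 10.51 on the other 8 region arrays. The mean signal of the hybridization spike-in controls was 13.70 on urogenital sinus replicate 1, 13.39, 13.35 and 12.67 on urethra replicates 1, 2 and 6, and 12.17 to 12.44 on the bladder arrays. Every bladder array thus lay under every urethra array in this measure. The log2 ratio of 3' to 5' beta-actin probe sets, a sign of RNA length, was 4.04 on bladder replicate 8 and 3.42 on urethra replicate 1. Urogenital sinus replicate 1 had the lowest mean correlation with its own region, 0.889 across all probe sets. The 3 arrays of the reference RNA, each in another title style, correlated with one another at 0.890 to 0.899. Pairs of arrays from different regions ranged from 0.840 to 0.954, so repeats of the reference were no closer than some of these pairs. Whether title style produced this was not tested. The first 3 principal components of the region arrays held 36.0%, 18.1% and 14.2% of the variance.

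**Figure D1:**
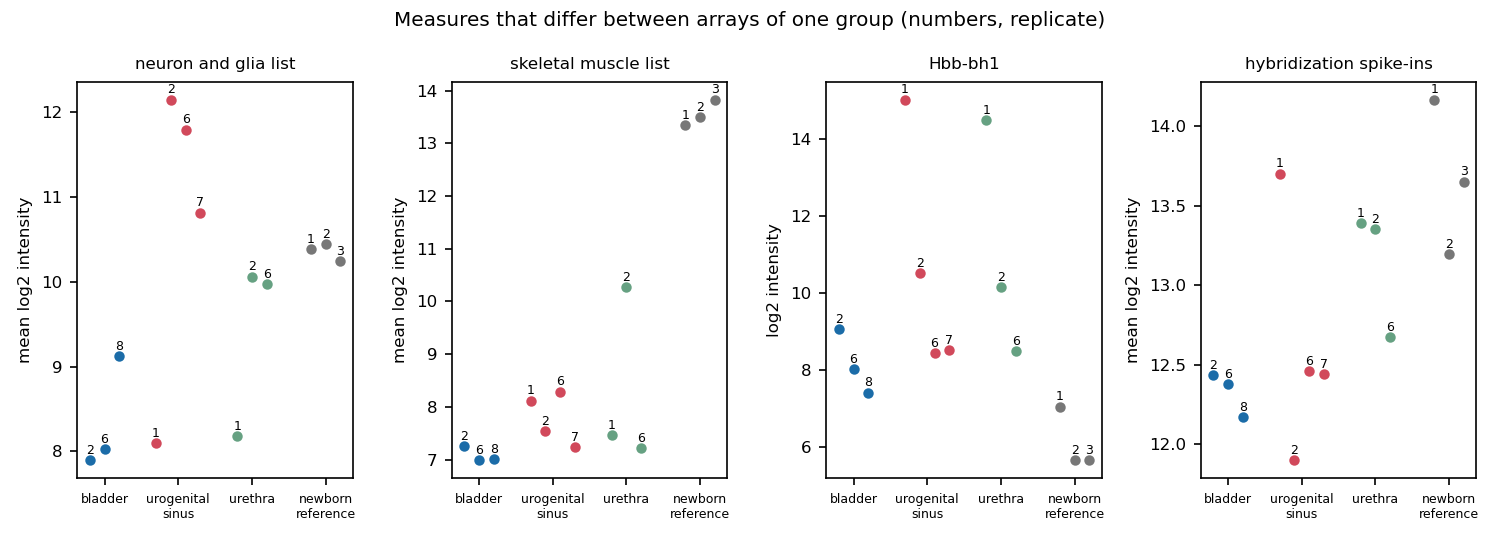
Mean log2 intensity of the neuron and glia list, mean of the skeletal muscle list, Hbb-bh1 level and mean spike-in signal (log2 intensity) on each array, with each point an array marked by its replicate number. Urogenital sinus replicate 1 stands apart with a neuron and glia mean of 8.10 against 10.82 to 12.15 on the other 3 sinus arrays, and with Hbb-bh1 at 15.04.

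The bladder was compared with the urogenital sinus first. Genes of contractile smooth muscle were higher in the bladder (n = 3) than in the sinus (n = 4). Actg2 itself stood at 13.67 ± 0.26 (SD) in the bladder and 9.26 ± 1.15 in the sinus, a log2 difference of 4.41 (SE 0.54, adjusted p = 0.00551) or 21.3-fold. Myh11, the smooth muscle myosin heavy chain, differed by 4.62 (SE 0.78, adjusted p = 0.0187), Tagln, an actin-binding protein of smooth muscle, by 3.90 (SE 0.59, adjusted p = 0.0123), and Acta2, smooth muscle alpha-actin, by 2.37 (SE 0.44, adjusted p = 0.0262). In the opposite direction, transcription factors of the genital tubercle were lower in the bladder, with Sall1 at -4.65 (SE 0.78, adjusted p = 0.0186) and Isl1 at -3.57 (SE 0.50, adjusted p = 0.0102). Krt5, a keratin of basal epithelial cells, was lower in the bladder by a log2 difference of -3.39 (SE 0.46, adjusted p = 0.00908).

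Of the 18 smooth muscle genes, 8 were higher in the bladder, 0 lower and 10 not called; adjusted over the list alone, 15 were higher and 1 lower. The list median was 1.68 against -0.19 for all genes tested (camera adjusted p = 1.12e-14; adjusted p = 0.0491 with an estimated correlation). The region was chosen by Actg2 fluorescence, so the direction of this list is not independent of the dissection. The largest higher values included 2 other called genes. Tnnt2, the cardiac form of troponin T, was higher by 5.90 (SE 0.67) and Myom1, a protein of the sarcomere M-band, by 3.92 (SE 0.37). The remaining genes with the largest higher values were Gbp2, an interferon-induced GTPase (4.69), the collectin Colec10 (3.90), the amine oxidase Aoc3 (3.61, at least 5.23-fold), the protease inhibitor Serpinb1a (3.51, and 0.53 on its other probe set) and the orphan nuclear receptor Nr4a3 (3.49). Their adjusted p-values lay between 0.00294 and 0.0119. The extracellular matrix list had 1 of 23 members higher, the proteoglycan Lum at 2.26 (SE 0.42), and 9 higher and 1 lower when adjusted over the list alone. Its median was 0.73 (camera adjusted p = 2.34e-06; adjusted p = 0.123 with an estimated correlation). Of 21 cell cycle genes, 1 was higher, the mitotic kinase Aurkb at 1.06 (SE 0.19), and 4 when adjusted over the list alone. The cell cycle median was 0.53 (camera adjusted p = 1.15e-07; adjusted p = 0.0240 with an estimated correlation).

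Genes of genital tubercle and urethral plate development were lower in the bladder. Of 18 such genes, 7 were lower and 11 not called, and 9 were lower when adjusted over the list alone; the list median lay 1.02 under that of all genes tested, and the mean was -1.56 (camera adjusted p = 2.34e-06; adjusted p = 0.0240 with an estimated correlation). Besides Sall1 and Isl1 these included Eya1, a transcriptional coactivator, at -3.07 (SE 0.54) and its partner Six2 at -2.91 (SE 0.61). In the Wnt pathway 3 of 28 members were lower, and 9 were lower and 1 higher when adjusted over the list alone. They were the Wnt agonist Rspo2 (-3.29, SE 0.41, and -0.38 on its other probe set), the ligand Wnt5a (-2.39, SE 0.35) and the antagonist Dkk1 (-2.10, SE 0.39). The Wnt median was -0.94 (camera adjusted p = 0.000672; adjusted p = 0.0491 with an estimated correlation). In the BMP pathway 3 of 17 were lower, and 5 when adjusted over the list alone: the antagonist Chrdl1 (-2.85, at least 3.36-fold lower), the ligand Bmp7 (-1.80) and the target Msx1 (-1.55). The BMP median was -1.12 (camera adjusted p = 0.0198; adjusted p = 0.146 with an estimated correlation). The retinoic acid list had 1 of 14 lower, the binding protein Crabp1 (-3.39, at least 4.37-fold lower), and 7 when adjusted over the list alone. Its median was -0.90 (camera adjusted p = 0.000403; adjusted p = 0.0491 with an estimated correlation).

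None of the 19 anterior and central Hox genes was called, 10 were lower when adjusted over the list alone, and the median was -1.39 (camera adjusted p = 2.40e-05; adjusted p = 0.0491 with an estimated correlation). The member with the smallest p was Hoxb3, at -2.31 (SE 0.55, adjusted p = 0.0588). In bladder against urogenital sinus the 9 posterior Hox genes had a median of -0.54, which turned to 0.05 with the arrays centred on their medians, and 1 was lower, Hoxd11 (-1.74, at least 1.47-fold lower). Their camera adjusted p was 0.0129 (adjusted p = 0.0887 with an estimated correlation); it was 0.0645 without bladder replicate 2 and 0.0634 without urogenital sinus replicate 7. Of 19 general epithelial genes 1 was lower, Krt5, and 2 when adjusted over the list alone, with a median of -0.74 (camera adjusted p = 0.000687; adjusted p = 0.370 with an estimated correlation). The nephric and reproductive duct list had 1 of 12 lower, and 3 when adjusted over the list alone: the member called was Gata3, a transcription factor of duct and urothelial cells (-2.44, SE 0.35). Its median was -1.34 (camera adjusted p = 0.00162; adjusted p = 0.123 with an estimated correlation).

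Of the 18 members of the neuron and glia list 1 was called, the neuronal RNA-binding protein Elavl3 at -3.70 (SE 0.65, adjusted p = 0.0211; -0.67 on its other probe set), and 7 were lower when adjusted over the list alone. The median was -2.45 with 18 of 18 values under 0 (camera adjusted p = 2.40e-05; adjusted p = 0.400 with an estimated correlation). The list mean was 7.89 to 9.12 on the bladder arrays, 10.82 to 12.15 on urogenital sinus replicates 2, 6 and 7, and 8.10 on urogenital sinus replicate 1. Without that array the list median was -3.75 and 7 members were called. Besides Sall1, the largest lower values of called genes were those of the splicing regulator Rbfox1 (-4.43), the leucine-rich repeat protein Lrrn3 (-4.45), the choline transporter Slc5a7 (-4.32), the potassium channel subunit Dpp10 (-4.31), the calcium-binding protein Caln1 (-4.78), the lipase-related Pnliprp1 (-5.50), histidine decarboxylase Hdc (-5.41), the tight junction protein Cldn11 (-4.43) and the transcription factor Sp8 (-4.33), which was at the floor on the 3 bladder arrays. Every bladder array lay under the filter level for 5 of these genes, of which Lrrn3 was at least 9.73-fold, Slc5a7 7.55-fold and Sp8 6.01-fold lower. No such bound is given for Rbfox1 and Caln1, for which another probe set gave -0.51 and -2.26. Other probe sets were also over 1.5 times smaller in log2 for Acta2 (1.54), Greb1 (-1.31) and Lor (-0.82).

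Endothelial genes had 0 of 15 called in limma, with a median of 0.25 (camera adjusted p = 0.0220; adjusted p = 0.434 with an estimated correlation). That call for bladder against urogenital sinus was lost without bladder replicate 2 (0.113), urogenital sinus replicate 6 (0.0519) or urogenital sinus replicate 7 (0.207). The smallest p in it belonged to the angiopoietin receptor Tek, at 2.10 (SE 0.56, adjusted p = 0.0868). The other 14 lists passed no camera test, with adjusted p from 0.154 to 0.944. Among them, 2 of 7 steroid response genes were lower, Greb1 (-2.83) and the nuclear receptor Nr2f1 (-1.68), and that list passed without bladder replicate 8 (0.0241) or urogenital sinus replicate 1 (0.0305). Of 10 epidermal genes, the cornified envelope gene Lor was lower (-2.06) and Ivl higher (2.12). Of 14 urothelial differentiation genes only Gata3 was lower; that list had a median of -0.07 and a mean of 0.24. In limma 0 members were called in the lists for hedgehog (median -0.26), FGF (-0.58), skeletal muscle (-0.79), cartilage and bone (-0.58), erythroid cells (-0.49), macrophages and leukocytes (-0.35), intestine (-0.30), mesothelium (0.39), gonad and adrenal (-0.56), liver (-0.55), and immediate early and heat shock genes (-0.00).

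In total 382 of 15019 genes were called by limma, 122 higher and 260 lower in the bladder, and 2588 had an unadjusted p under 0.05 against 751 by chance. The groups did not overlap on any array for 2684 genes (17.9%, against 5.71% by chance). The split of the calls followed the scaling: quantile normalization gave 96 higher and 103 lower, and centring on array medians 217 higher and 88 lower. Array weights gave 2668 calls. With title number as a fixed replicate block 22 of the 41 named genes stayed called. With title style as a fixed block 467 genes were called and Actg2 differed by 4.34, and within each of the 2 styles that hold both regions 100% of the 382 genes had that direction. The genes were called on these same arrays, so the within-style share is nearly fixed by their selection and does not test for an effect of style. Leaving out 1 array moved the count to 49, 46 and 193 (bladder replicates 2, 6 and 8), 647, 132, 125 and 248 (urogenital sinus replicates 1, 2, 6 and 7) or 236 (urethra replicate 6). Of the 41 named genes called, 10 stayed called whichever array was left out, and 11 were still called without bladder replicate 2 as without bladder replicate 6.

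**Figure D2:**
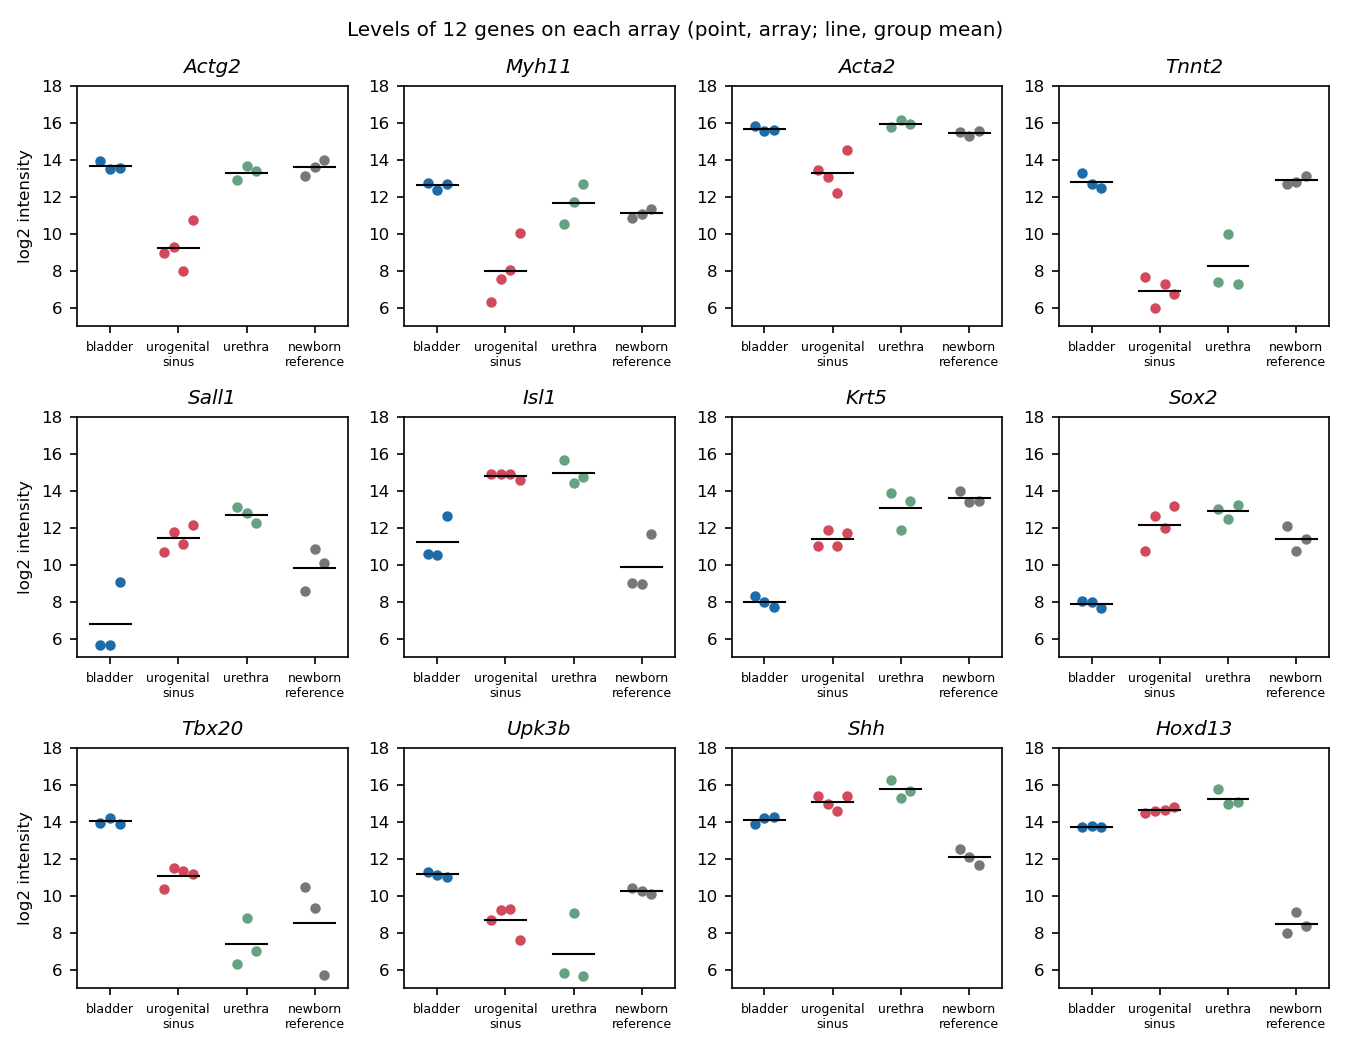
Log2 intensity of 12 genes on each array (points) with the mean of each group (lines), for bladder, urogenital sinus, urethra and newborn reference. Actg2 averages 13.67 in the bladder, 13.31 in the urethra and 9.26 in the urogenital sinus, and Tbx20 averages 14.03 in the bladder and 7.39 in the urethra.

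Between the urethra and the urogenital sinus, 2 of 15019 genes were called by limma. Clca3b, of a family of chloride channel regulators, was higher in the urethra at 8.01 ± 0.34 (SD, n = 3) against 5.72 ± 0.14 (n = 4), a difference of 2.29 (SE 0.22, adjusted p = 0.0161) or at least 1.54-fold. Every sinus array but replicate 1 lay at the floor of 5.65 for Clca3b, so the floor limits its spread there. Pdzk1, a scaffold protein of membrane transporters, was lower (-1.70, SE 0.19, adjusted p = 0.0329). Both Pdzk1 means lay under the filter level, so no fold is given. Neither gene was called with no floor or with the floor at the 40th percentile. Actg2 was 13.31 ± 0.39 in the urethra, a difference of 4.05 (SE 0.54, adjusted p = 0.0827) from the sinus. Of the 18 smooth muscle genes 0 were called, 13 were higher when adjusted over the list alone, and the median was 1.54 (camera adjusted p = 1.17e-12; adjusted p = 0.138 with an estimated correlation). This list again is not independent of the dissection by Actg2 fluorescence.

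Another 5 lists passed the camera test for urethra against urogenital sinus, and no member of them was called. General epithelial genes had a median of 0.49 (camera adjusted p = 0.00344; adjusted p = 0.601 with an estimated correlation) and 2 of 19 were higher when adjusted over the list alone. Krt15, a basal keratin, had the smallest p of that list, at 2.32 (SE 0.48, adjusted p = 0.147). That call was lost without urethra replicate 1 (0.122), without urethra replicate 6 (0.0739) and without both arrays numbered 1 (0.0710), a setting chosen after seeing the data. BMP pathway genes had a median of -0.63 with 6 of 17 lower when adjusted over the list alone (camera adjusted p = 0.000101; adjusted p = 0.138 with an estimated correlation), and the member with the smallest p was the transcriptional inhibitor Id4 (-2.48, SE 0.45, adjusted p = 0.105, with another probe set at -1.36). The nephric and reproductive duct list had a median of -1.32 with 2 of 12 lower when adjusted over the list alone (camera adjusted p = 0.00185; adjusted p = 0.227 with an estimated correlation). The smallest p in it belonged to Wt1, a transcription factor of kidney and mesothelium, at -3.22 (SE 0.63, adjusted p = 0.126). Anterior and central Hox genes had a median of -0.89 (camera adjusted p = 0.000165; adjusted p = 0.138 with an estimated correlation), with Hoxb9 at -1.35 (SE 0.47, adjusted p = 0.374). Neuronal and glial genes had a median of -1.42 (camera adjusted p = 0.000165; adjusted p = 0.601 with an estimated correlation), with the neural crest transcription factor Hand2 at -2.11 (SE 0.49, adjusted p = 0.20), which was 0.40 with title style as a fixed block.

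The remaining 21 lists had 0 called members in limma and camera adjusted p from 0.116 to 0.986. Skeletal muscle genes, with a median of 0.65, averaged 10.27 on urethra replicate 2 against 7.46 and 7.21 on urethra replicates 1 and 6. That list passed the camera test when urogenital sinus replicate 6 (0.0410), urethra replicate 1 (0.000486) or urethra replicate 6 (0.00359) was left out, in urethra against urogenital sinus. Other lists passed it with 1 array left out: steroid response without urogenital sinus replicate 1 (0.0488), retinoic acid and Wnt without urethra replicate 1 (0.0349 and 0.0454), and cartilage and bone without urethra replicate 2 (0.0353). Under the other settings, 4 pairs of a list and a setting passed it with the sign kept although the list had not passed in the main fit. Such pairs numbered 9 for bladder against urethra and 4 for stage. An unadjusted p under 0.05 was found for 1559 genes, against 751 by chance. The groups did not overlap for 1235 genes (8.22%, against 5.71% by chance). No title style holds both urethra and sinus arrays, so no value within a style can be given. Array weights gave 664 calls. With title style as a fixed block 14 genes were called, all higher, of which 0 were among the 2 above; Actg2 differed by 3.21 (SE 0.85, adjusted p = 0.271). In that fit of urethra against urogenital sinus the camera adjusted p was 0.00411 for smooth muscle, 0.540 for both the epithelial and the anterior and central Hox lists and 0.0612 for the neuronal list. Leaving out 1 array gave 22 calls without urogenital sinus replicate 1, 5 without urogenital sinus replicate 7, 6 without urethra replicate 2, 1 without urethra replicate 6, and 0 without bladder replicate 2, 6 or 8, urogenital sinus replicate 2 or 6, or urethra replicate 1.

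Bladder and urethra, the 2 fluorescent regions, were then compared. Actg2 showed no difference that passed the test, at 0.36 (SE 0.57, adjusted p = 0.724). Tbx20 and Tbx18, both T-box transcription factors, were higher in the bladder: Tbx20 stood at 14.03 ± 0.17 (SD, n = 3) against 7.39 ± 1.27 (n = 3), a difference of 6.64 (SE 0.56, adjusted p = 0.00174), and Tbx18 differed by 5.37 (SE 0.97, adjusted p = 0.0196). The urethra mean of Tbx20 lay near the filter level, its other 2 probe sets gave 1.32 and 4.62, and with title style as a fixed block it was 2.41 (adjusted p = 0.382), so its size is uncertain. The basal epithelial keratins Krt5 and Krt15 were higher in the urethra, with Krt5 at -5.06 (SE 0.49, adjusted p = 0.00174) and Krt15 at -4.43 (SE 0.51, adjusted p = 0.00337) in the bladder relative to it. Sox2, a transcription factor of progenitor cells, was also lower in the bladder, at -5.00 (SE 0.53, adjusted p = 0.00230), as was Sall1 at -5.92 (SE 0.83, adjusted p = 0.00756).

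Of 19 general epithelial genes, 4 were lower in the bladder and 8 when adjusted over the list alone, with a median of -1.15 against -0.25 for all genes tested (camera adjusted p = 7.19e-05; adjusted p = 0.341 with an estimated correlation). The others called were Krt14 (-2.28) and the claudin Cldn3 (-3.33, at least 5.25-fold lower). Genes of genital tubercle and urethral plate had 5 of 18 lower and 8 when adjusted over the list alone, with a median of -0.98 (camera adjusted p = 0.000815; adjusted p = 0.103 with an estimated correlation). Besides Sall1 they included Isl1 (-3.69, SE 0.53), Six2 (-3.63, SE 0.65) and Hoxd13, a regulator of genital and limb patterning (-1.53, SE 0.23). With title style as a fixed block, 6 of the 58 named genes called for bladder against urethra stayed called, so the size of single members can depend on that setting. The retinoic acid list had 4 of 14 lower and 10 when adjusted over the list alone, with a median of -1.35 (camera adjusted p = 0.000362; adjusted p = 0.103 with an estimated correlation). They were the synthesis enzyme Aldh1a1 (-4.53, SE 0.74), the binding proteins Crabp1 (-3.30, at least 4.12-fold lower) and Crabp2 (-1.57), and the receptor Rarb (-1.79). Extracellular matrix genes had 3 of 23 higher and 1 lower, and 5 higher and 2 lower when adjusted over the list alone, with a median of 0.59 (camera adjusted p = 0.000458; adjusted p = 0.341 with an estimated correlation). Lum (3.30, SE 0.45), the collagen Col14a1 (1.85, SE 0.32) and the proteoglycan Bgn (1.54, SE 0.37) were higher in the bladder, and tenascin C, Tnc, was lower (-2.78, SE 0.47). The cell cycle list had 1 of 21 higher, Aurkb (0.96, SE 0.20), and a median of 0.24 (camera adjusted p = 0.00156; adjusted p = 0.161 with an estimated correlation).

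The hedgehog, Wnt and BMP lists each had called members in both directions and passed no camera test. In the hedgehog list 1 of 12 was higher and 2 were lower (camera adjusted p = 0.918): the ligand Shh was lower in the bladder (-1.63, SE 0.30), as was its inhibitor and target Hhip (-2.00, SE 0.44), and the co-receptor Gas1 was higher (1.00, SE 0.23), though it stood at -0.33 with title style as a fixed block. In the Wnt list 1 of 28 was higher and 5 were lower (camera adjusted p = 0.0987), among them Rspo2 (-2.53), Wnt10a (-2.82), Sfrp4 (-1.76, at least 1.75-fold lower) and the target Axin2 (-1.24). In the BMP list 5 of 17 were higher and 2 lower, with a median of -0.56 while the camera direction was upward (camera adjusted p = 0.886). Bmper, a secreted BMP modulator, was higher (3.56, SE 0.52), as were Id2 (1.18) and Bmp5 (1.28), and Bmp7 was lower (-2.49, SE 0.38). Over the alternative settings Bmper ranged from 1.45 to 4.03, with limma adjusted p up to 0.579, so its size is uncertain. Of 14 urothelial genes, the uroplakin Upk3b was higher (4.32, SE 0.84), a gene that also marks mesothelium and was the 1 of 10 mesothelial genes called; Gata3 (-2.75) and Klf5 (-1.29) were lower. That list had a median of -0.52 and a mean of 0.08.

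Single members were called in other lists of bladder against urethra. They were creatine kinase Ckb of the smooth muscle list (2.54), the endothelial receptor Kdr (2.04), the macrophage receptor Mrc1 (2.10), Hoxb2 (-1.36), Gata3 of the duct list and the stress-response factor Jun (-1.54). The posterior Hox list had 2 of 9 lower, Hoxd13 and Hoxd11 (-1.84, at least 1.58-fold lower). In cartilage and bone, Col2a1 was lower (-3.09, at least 4.12-fold) and Hapln1 higher (2.06), and in epidermis Lor (-1.90) and Sbsn (-1.85) were lower. The neuronal list had 0 of 18 called in limma, with a median of -1.07 (camera adjusted p = 0.445), and passed without urethra replicate 1 (0.0464). The skeletal muscle list had 0 of 20 called, with a median of -1.25 (camera adjusted p = 0.146), and passed without urethra replicate 1 (0.00346) or urethra replicate 6 (0.0118). The Wnt list passed without bladder replicate 8 (0.0223) and the mesothelial list without urethra replicate 2 (0.0496). No member was called in the FGF, steroid response, erythroid, intestine, gonad and adrenal, or liver lists, with camera adjusted p from 0.219 to 0.987.

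The further genes with the largest higher values in the bladder were Colec11 (6.14), the protocadherin Pcdh8 (5.15), Gbp2 (4.80), Tnnt2 (4.58), Lyve1, a hyaluronan receptor of lymphatic vessels and macrophages (4.23), the scavenger receptor Scara5 (4.15) and Nr4a3 (4.10). Those with the largest lower values were Pdlim4 (-5.21), the desmosome protein Pkp1 (-5.03, at least 13.5-fold lower), Lhx8 (-4.94, at least 11.9-fold lower), the neurotrophic factor Gdnf (-4.91, at least 10.2-fold lower), Sp8 (-4.89, at least 8.90-fold lower), the carbonyl reductase Cbr2 (-4.86, at least 13.6-fold lower) and the sodium channel Scn3a (-4.73). Another probe set of the gene had the opposite sign for Scara5 (-0.31), Klf5 (0.26), Id2 (-0.83), Bmp5 (-0.32) and Hapln1 (-0.00). Besides Tbx20, it was over 1.5 times smaller in log2 for Colec11 (3.36), Tbx18 (2.78), Lyve1 (1.52), Krt14 (-0.41), Hhip (-1.32), Gas1 (0.26), Rspo2 (-0.74), Col14a1 (0.86), Lor (-0.87) and Sbsn (-0.00).

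**Figure D3:**
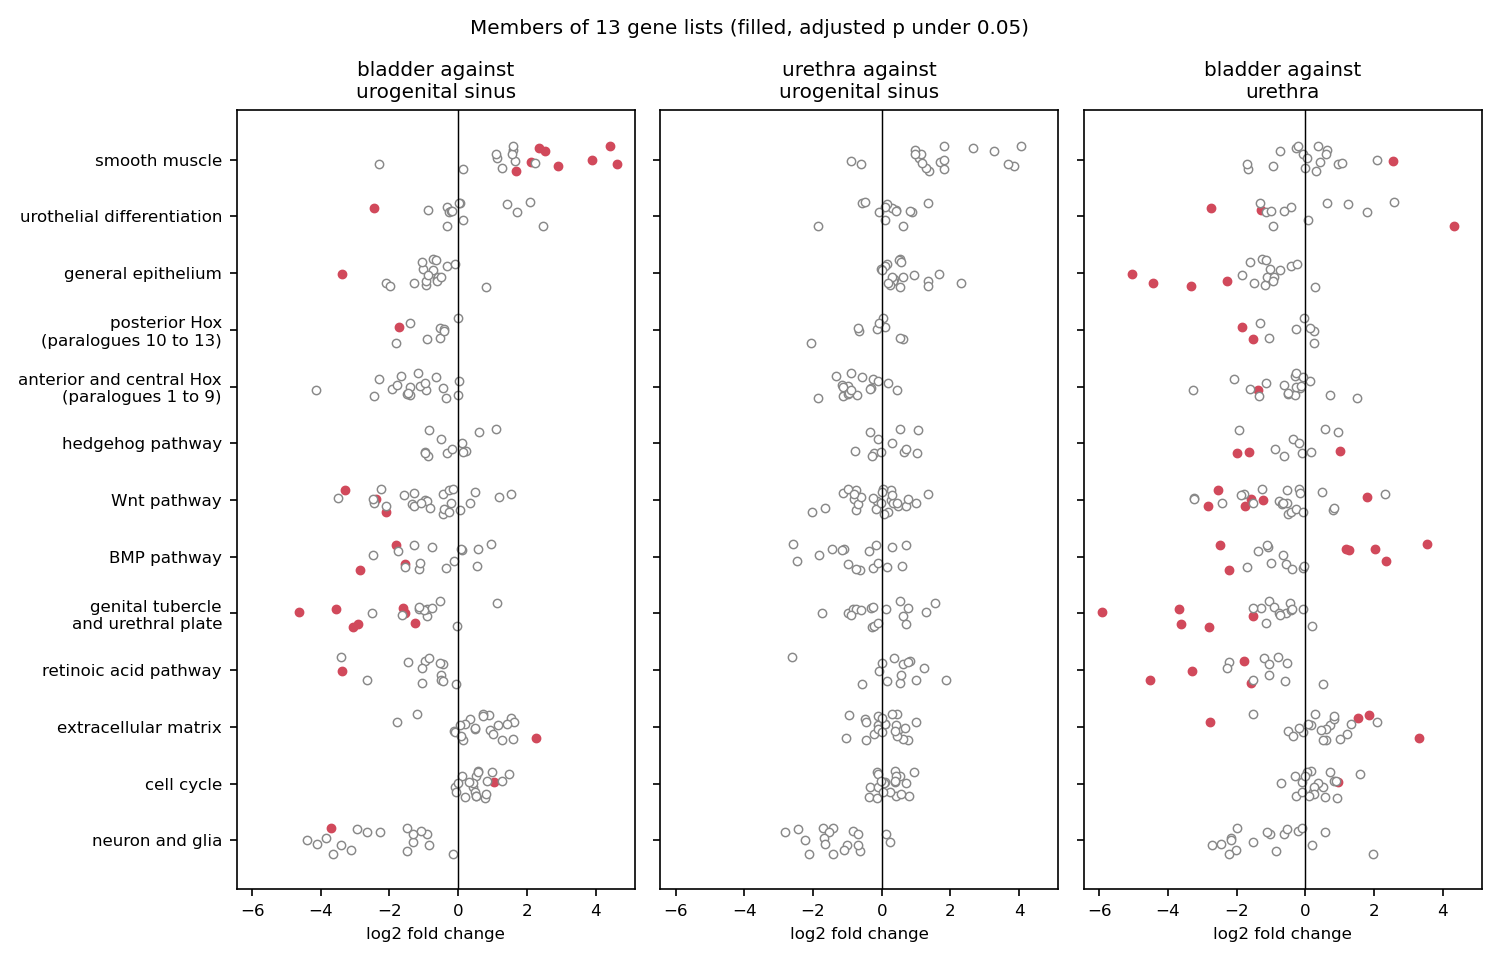
Log2 fold change of each tested member of 13 gene lists in the 3 comparisons between regions; each point is a gene, and filled points have an adjusted p under 0.05. Smooth muscle members have a median of 1.68 for bladder against urogenital sinus, 1.54 for urethra against urogenital sinus and 0.18 for bladder against urethra.

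Between bladder and urethra 651 of 15019 genes were called by limma, 257 higher and 394 lower in the bladder, with 3655 at an unadjusted p under 0.05 against 751 by chance. The groups did not overlap for 5185 genes (34.5%, against 10% by chance). Quantile normalization gave 225 higher and 184 lower, and centring on array medians 238 higher and 90 lower. Array weights gave 1873 calls. Spike-in signal averaged 12.33 ± 0.14 (SD, n = 3) in the bladder and 13.14 ± 0.40 (n = 3) in the urethra. With it as a covariate, a setting chosen after seeing the data, 447 genes were called, 287 of them among the 651, and 35 of the 58 named genes stayed called. With title number as a fixed replicate block 18 of the 58 named genes stayed called. No title style holds both regions. With title style as a fixed block 55 genes were called, 4 higher and 51 lower, 28 of them among the 651, and 6 of the 58 named genes stayed called; for bladder against urethra the genital tubercle list then had a camera adjusted p of 0.143. In that fit Krt5 stood at -5.31 (SE 0.86, adjusted p = 0.0363), Sall1 at -5.20 (SE 0.90, adjusted p = 0.0363) and Tbx20 at 2.41 (SE 1.03, adjusted p = 0.382). Leaving out 1 array moved the count to 142, 111 and 225 (bladder replicates 2, 6 and 8), 236, 250 and 344 (urethra replicates 1, 2 and 6), 1292 (urogenital sinus replicate 1) or 417 (urogenital sinus replicate 6), and 18 of the 58 named genes stayed called in each of the 10 such fits.

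The mean of the 3 regions was set against the newborn reference, which holds every organ of the mouse. Fgb and Fgg, liver genes for fibrinogen chains, differed by -10.18 (SE 0.25, adjusted p = 2.23e-08, at least 352-fold lower) and -10.25 (SE 0.66, adjusted p = 3.39e-06). Fabp1, a fatty acid-binding protein of liver and intestine, differed by -10.32 (SE 0.44, adjusted p = 1.87e-07), the liver-derived Igfbp1 by -10.08 (SE 0.70) and Myh8, the perinatal myosin of skeletal muscle, by -9.79 (SE 1.19). Most region arrays lay at the floor for Fgb, Fgg, Fabp1 and Igfbp1, so the sizes of these 4 differences are set by the floor and have no order. Of the genes that were higher, Hoxd13 was 14.54 ± 0.67 (SD, n = 10) in the regions and 8.50 ± 0.59 over the 3 repeats of the reference, a difference of 6.05 (SE 0.30, adjusted p = 5.41e-07), and Myocd, the coactivator of smooth muscle genes, differed by 6.01 (SE 1.61, adjusted p = 0.0313).

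The intestine list had 11 of 11 members lower, with a median of -5.09 (camera adjusted p = 3.73e-12; adjusted p = 0.0196 with an estimated correlation), including villin, Vil1 (-6.20, at least 24.0-fold lower), and Fabp2 (-9.08). The epidermis list had 9 of 10 lower and a median of -5.82 (camera adjusted p = 3.73e-12; adjusted p = 0.00895 with an estimated correlation), including filaggrin, Flg (-8.23, at least 89.8-fold lower), and Krt10 (-6.54). The liver list had 9 of 10 lower, and 10 when adjusted over the list alone, with a median of -8.07 (camera adjusted p = 1.87e-11; adjusted p = 0.0764 with an estimated correlation), including Ahsg (-9.78, at least 314-fold lower). Skeletal muscle had 16 of 20 lower, and 20 when adjusted over the list alone, with a median of -5.25 (camera adjusted p = 1.11e-11; adjusted p = 0.175 with an estimated correlation), including creatine kinase Ckm (-8.66, but -1.59 on its other probe set). Cartilage and bone had 10 of 16 lower, and 13 when adjusted over the list alone, with a median of -3.10 (camera adjusted p = 3.16e-08; adjusted p = 0.0613 with an estimated correlation), including Ibsp of bone matrix (-7.19, and -3.05 on its other probe set). Macrophage and leukocyte genes had 7 of 14 lower, and 12 when adjusted over the list alone, with a median of -2.18 (camera adjusted p = 4.80e-05; adjusted p = 0.195 with an estimated correlation), including lysozyme Lyz2 (-3.77).

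Cell cycle genes were higher in the regions, 9 of 21 over all genes and 16 when adjusted over the list alone, with a median of 1.07 (camera adjusted p = 3.16e-08; adjusted p = 0.0196 with an estimated correlation), such as Top2a (1.81, SE 0.28) and Aurkb (1.99, SE 0.26). The posterior Hox list had 3 of 9 higher and 1 lower, with a median of 1.19 (camera adjusted p = 0.0124; adjusted p = 0.0897 with an estimated correlation): Hoxd10 (4.16) and Hoxa10 (2.10) were higher beside Hoxd13, and Hoxc13, which is known from hair and nails, was lower (-3.08, at least 2.56-fold). The hedgehog list had 3 of 12 higher, with a median of 0.84 (camera adjusted p = 0.00242; adjusted p = 0.0897 with an estimated correlation): Shh (2.89), the mesenchymal target Foxf1 (3.48) and the receptor Ptch1 (1.29). Genital tubercle genes had 5 of 18 higher, and 6 higher and 1 lower when adjusted over the list alone, with a median of 0.64 (camera adjusted p = 0.00988; adjusted p = 0.0897 with an estimated correlation), such as Tbx2 (3.73), Tbx3 (3.15) and Isl1 (3.80). The extracellular matrix list had 1 of 23 higher, Vcan (1.15), and 2 lower, Postn (-3.07) and Bgn (-1.89), with a median of -0.82 (camera adjusted p = 0.0381; adjusted p = 0.463 with an estimated correlation). In the mean of the 3 regions against newborn reference that call was lost with arrays centred on their medians (0.134), without urethra replicate 2 (0.0619) and without newborn reference replicate 1 (0.0965).

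The other 16 lists passed no camera test, with adjusted p from 0.0819 to 0.954. Called members went both ways in the smooth muscle list, with 3 higher and 3 lower of 18: Synpo2 (2.59) and Pgm5 (2.16) were higher, and Des (-3.92) and Tpm1 (-3.30), both also expressed in striated muscle, were lower. Retinoic acid genes had 3 higher and 1 lower of 14: Rarb (3.75), the synthesis enzyme Aldh1a2 (3.16) and Crabp2 (2.27) were higher, and the plasma carrier Rbp4 was lower (-6.01). Erythroid genes had 1 higher and 3 lower of 9. Hbb-y, an embryonic globin, was higher (5.97), and Rhag (-3.58, at least 4.61-fold lower), Alas2 (-3.32) and Slc4a1 (-4.72) were lower. General epithelium had 1 higher, Cldn6 (2.93), and 4 lower of 19, such as Krt14 (-6.34). The Wnt list had 4 higher and 1 lower of 28, among them Rspo2 (3.84) and Fzd2 (2.09) higher and Sfrp4 (-3.08) lower, and the BMP list 4 higher and 1 lower of 17, among them Bmp4 (2.43) higher and Bmp2 (-2.04) lower. Foxa1 was higher (3.83) and Krt20 lower (-3.10) among 14 urothelial genes. Steroid response had 3 of 7 higher, such as Nr2f2 (2.28), and the heat shock and immediate early list 3 of 14 lower, such as Hspa1a (-2.50) and Fos (-2.14); for the mean of the 3 regions against newborn reference, that last list had a camera adjusted p of 0.0476 without newborn reference replicate 3. Hoxa9 (2.78) and Hoxd8 (1.40) were higher among 19 anterior and central Hox genes, Hand2 (3.11) among 18 neuronal genes, and Aldh1a2 also as the 1 called of 10 mesothelial genes. Fgfr4 was lower among 13 FGF genes (-2.38) and Hsd3b1 among 7 gonad and adrenal genes (-3.98), and the duct and endothelial lists had 0 called members in limma. The further genes with the largest higher values were the metalloprotease Adamts20 (6.08) and the transcription cofactor Dach2 (4.69).

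For 8 genes named against the reference another probe set had the opposite sign: Synpo2 (-2.35, itself called), Tpm1 (1.94), Hoxa9 (-0.35), Ptch1 (-1.27), Rspo2 (-0.05), Greb1 (-0.70), Vcan (-0.35) and Top2a (-0.91). It was over 1.5 times smaller in log2 for Myocd (1.40), Dach2 (2.69), Des (-0.84), Krt14 (-0.80), Hoxd8 (0.80), Foxf1 (1.52), Fzd2 (1.08), Fgfr4 (-0.30), Tbx3 (0.34) and Nr2f2 (1.02), besides Ckm and Ibsp. The same held for list members called but not described above: Apoh (-7.92, other -1.354), Csf1r (-2.747, other -1.445), Kif11 (1.953, other 0.755) and Cenpa (1.569, other 0.592). Without a floor Ckm was represented by its other probe set and was not called (adjusted p = 0.203). With the mean of a gene's probe sets in place of 1 probe set, Ptch1 was 0.26 (adjusted p = 0.892) and Top2a 0.45 (adjusted p = 0.669), and 68 of the 82 named genes were still called.

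**Figure D4:**
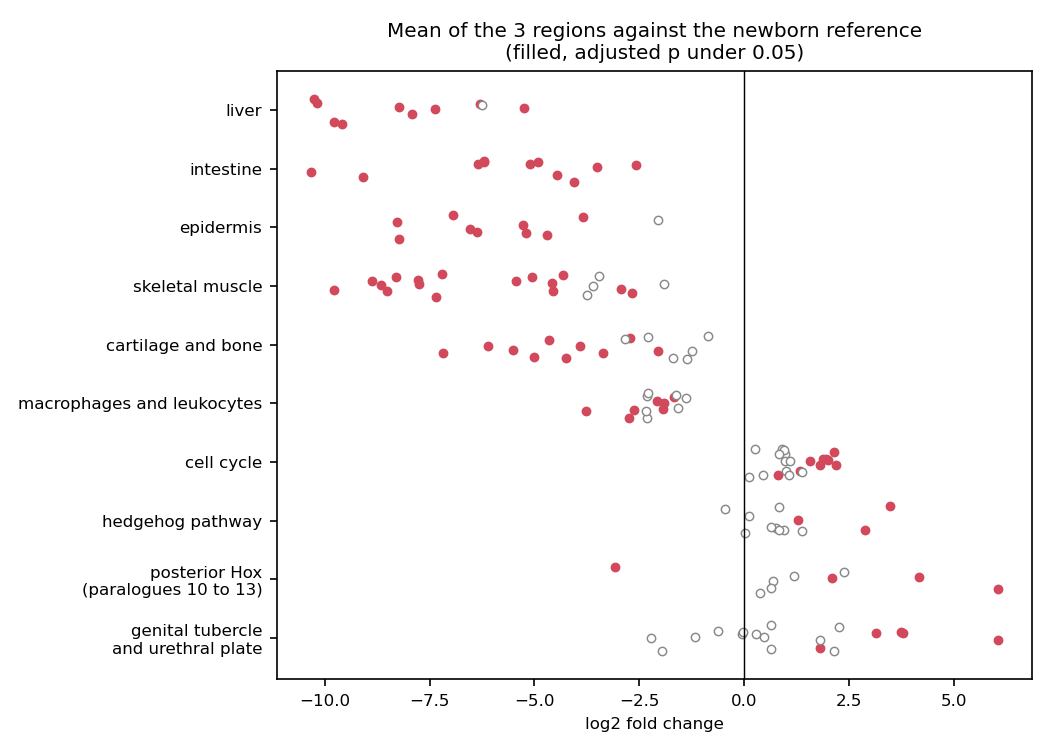
Log2 fold change, mean of the 3 regions minus newborn reference, of each tested member of 10 gene lists; each point is a gene, and filled points have an adjusted p under 0.05. Liver members have a median of -8.07, skeletal muscle members -5.25 and cell cycle members 1.07.

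In this comparison 2366 of 15019 genes were called by limma, 815 higher and 1551 lower in the regions, with 4221 at an unadjusted p under 0.05 against 751 by chance. The reference entered as 1 sample, so its spread was taken from the region arrays. Leaving out any 1 of the 13 arrays gave between 1944 and 3079 calls, and 68 of the 82 named genes stayed called in every such fit. With the 3 reference arrays as 3 samples 5550 genes were called, and 5653 when title style was added as a fixed block; array weights gave 5119. The age of the mice, the amount of each organ in the pool and the dissection all differ between the regions and the reference.

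Theiler stages 21 and 22 were compared over the region arrays (n = 5 each) with region as a covariate. Of 15019 genes 0 were called by limma, with a smallest adjusted p of 0.0770, while 3830 had an unadjusted p under 0.05 against 751 by chance. The absence of calls depended on the setting: 366 genes were called with no floor, 498 with robust eBayes and 1421 with array weights. In the 27 lists 0 members were called over all genes, and camera adjusted p lay between 0.133 and 0.991. The smallest belonged to neuronal and glial genes, with a median of 0.67, and that list had a camera adjusted p of 6.70e-05 without urogenital sinus replicate 2 in Theiler stage 22 against 21. Array measures differed in their stage means: spike-in signal averaged 12.96 at stage 21 and 12.42 at stage 22, and Hbb-bh1 11.86 and 8.18. The spike-in values of stage 21, 11.90 to 13.70, enclosed those of stage 22, 12.17 to 12.67. Hbb-bh1 did not overlap, at 9.06 to 15.04 and 7.41 to 8.51. The stages also hold different numbers of arrays of each region, for which these means were not adjusted. Without urogenital sinus replicate 7, 3 genes were called, and title style as a fixed block left 0 calls and 2364 genes at an unadjusted p under 0.05.

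Scaling shifted the median of all genes in each comparison. As deposited, the median log2 fold change of all genes tested was -0.19 for bladder against urogenital sinus, 0.05 for urethra against urogenital sinus, -0.25 for bladder against urethra, -0.08 for the regions against the reference and -0.11 for stage. With quantile normalization these were 0.03, 0.06, -0.03, 0.11 and 0.02, and with arrays centred on their medians 0.40, 0.17, 0.22, 0.41 and 0.16. Of the named genes called, 27 of 41 were still called under quantile normalization and 30 under median centring for bladder against urogenital sinus. For bladder against urethra these were 35 and 34 of 58, and for the regions against the reference 82 and 68 of 82.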

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

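Of the tests below, the one of scaling against the direction of the calls was chosen after its result was seen, as was the use of median centring beside it, and the fits with spike-in signal or beta-actin ratio as a covariate were added after seeing the data. The second neuronal list was written after the first list's result was known and before its own values were computed.

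Neuronal and glial genes had a median of -2.45 for bladder against urogenital sinus, and of -3.75 without urogenital sinus replicate 1. Neither quantile normalization nor adjustment for array brightness removed it: the median was -2.01 under quantile normalization and -3.42 with spike-in signal as a covariate. A second list of 22 neuronal genes, of which 21 were tested and 0 belong to the other lists, had a median of -2.78 (-3.63 without that array); within regions its array means followed those of the first list over 10 arrays (Pearson r = 0.983, exact permutation p = 0.00347; Spearman rho = 0.988, p = 0.00463; r = 0.958 and p = 0.0417 without the 2 farthest arrays; 1 relation was computed). Among its most abundant genes, sinus and bladder means were 13.21 ± 1.57 and 11.21 ± 0.53 for Mllt11, with Nsg1 at 12.47 ± 0.65 against 11.76 ± 0.29, Kif5c at 13.18 ± 1.84 against 10.31 ± 1.42 and Elavl2 at 13.43 ± 1.77 against 9.67 ± 0.50 (SD, n = 4 and 3), and 9 of the 21 lay above the filter level on every bladder array. Differing amounts of neuronal tissue in the dissected pieces may underlie the pattern, and no sort removed such cells. The relation of the lists cannot decide this, since it was taken within regions and neuronal genes can move together under other causes too. Whether the pattern is innervation of the sinus or tissue taken along also stays open.

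The calls for bladder against urogenital sinus leaned to lower values, at 68.1%. With spike-in signal as a covariate the share was 73.3%, so this adjustment for array brightness did not reduce it. The share was 51.8% under quantile normalization and 28.9% with arrays centred on their medians, but both settings shift the median of all genes. The lean follows the scaling chosen, and whether scaling or a biological difference between the regions produced it cannot be told apart. Spike-in signal does not decide it: as scaled it averaged 12.33 ± 0.14 (SD, n = 3) in the bladder and 12.63 ± 0.76 (n = 4) in the sinus, a difference within its spread.

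Between Theiler stages 3830 genes had an unadjusted p under 0.05 and 0 were called by limma, although 366 were with no floor, 498 with robust eBayes and 1421 with array weights. Of the 54 splits of the arrays within regions 1 gave as many, the real one, and the highest other split gave 3385. With spike-in signal as a covariate 3017 genes remained at that level and with the beta-actin ratio 3676, so neither measure accounts for the whole excess. Stage itself, sex and other differences between embryos stay open and untested, since Xist and the Y-linked Eif2s3y and Uty differ between replicates 1, 2 and 7 and replicates 6 and 8, and replicate numbers do not cross the stages.

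Other splits of the arrays were counted for each comparison between regions. For bladder against urogenital sinus, 1 of 35 splits called as many genes as the real one, namely the real one itself, which called 382. The highest other, which set urogenital sinus replicates 2, 6 and 7 against replicate 1 and the bladder arrays, called 264. Ranking first of 35 is the lowest share these splits allow, so chance is less likely for the count of called genes but is not excluded. For the genes at an unadjusted p under 0.05, 4 of 35 splits reached the real 2588 and the highest other had 3302. For urethra against urogenital sinus, 4 of 35 splits called at least 2 genes and the highest other, which set the same 3 sinus arrays against replicate 1 and the urethra arrays, called 50. Chance cannot be excluded there, nor on the unadjusted count, which 8 of 35 splits reached, and a split with many times the real count points to a structure of the samples in which sinus replicate 1 stands apart. For bladder against urethra the 10 splits are too few for a share under 0.05; the real split, 1 of the 10, called 651 genes and the highest other 0.

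Among 174 measures on the 4 urogenital sinus arrays, which were array measures and levels of named genes, 15 had 1 array far from the other 3, all of them gene levels. In 4 of them the others lay above the floor, and chance alone gives about 1 in 20 of such measures. Caln1 was 11.95 on replicate 2 against 10.25 to 10.46, Isl1 14.61 on replicate 7 against 14.89 to 14.93, Nr2f1 11.56 on replicate 1 against 12.28 to 12.40, and Fos 10.30 on replicate 7 against 10.94 to 11.01. In the other 11 the remaining arrays lay at or next to the floor of 5.65, where any array off the floor stands apart, so these are not set against chance. On replicate 1 these were Clca3b (5.92), Fabp1 (6.87), Igfbp1 (7.68) and Dsg1a (6.73). On replicate 2 it was Serpinb1a (6.49). On replicate 6 these were Fgg (7.46), Fgb (5.89), Cnmd (6.25) and Calm4 (6.81), and on replicate 7 Ibsp (6.28) and Vil1 (5.79).

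Probe sets without a single gene symbol were outside the comparisons. When every probe set was tested, 25 of 5662 such probe sets were called for bladder against urogenital sinus (2 higher, 23 lower), 48 for bladder against urethra (14 higher, 34 lower) and 305 for the regions against the reference (103 higher, 202 lower). For urethra against urogenital sinus and for stage limma called 0 of them.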

How the results depend on the processing

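The fits without the 2 arrays numbered 1 and those with spike-in signal or beta-actin ratio as covariates were chosen after seeing the data. Where a count moved by over 1.5 times the cause was not tested, except that fewer arrays or more tested genes are part of some settings. For bladder against urogenital sinus (382 calls) the count was 199 with quantile normalization, 235 with no filter, 2668 with array weights, 236 with only the arrays of the 2 regions, 766 without the 2 arrays numbered 1 and 656 with the spike-in covariate. For bladder against urethra (651) it was 409 with quantile normalization, 328 with median centring, 1873 with array weights and 55 with title style as a fixed block. For the regions against the reference (2366) it was 5119 with array weights, 5550 with the reference arrays as 3 samples and 5653 with title style added. For urethra against urogenital sinus (2) it was 1 with quantile normalization, 7 with median centring, 11 with no floor, 7 with the floor at the 40th percentile, 4 with no filter, 1 with the filter at the 60th percentile, 1 without the intensity trend, 9 with robust eBayes, 664 with array weights, 17 with all 13 arrays, 14 with title style as a fixed block, 1 with stage as a covariate and 1 with the spike-in covariate. It was 0 with only the 2 regions, 0 without the arrays numbered 1 and 0 with the beta-actin covariate. The calls of urethra against urogenital sinus with no floor or with the floor at the 40th percentile included neither of the 2 main calls. For stage, limma called 0 genes in all settings except no floor (366), robust eBayes (498), array weights (1421) and 1 left-out array. With 1 array left out the counts ranged from 46 to 647, 0 to 22, 111 to 1292, 1944 to 3079 and 0 to 3, for bladder against urogenital sinus, urethra against urogenital sinus, bladder against urethra, the reference and stage.

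Title numbers as a replicate block gave 132 (fixed) and 669 (random) calls for bladder against urogenital sinus, 0 and 58 for urethra against urogenital sinus, and 140 and 1171 for bladder against urethra. Of the named genes called, the fixed block kept 22 of 41, 0 of 2 and 18 of 58 in these comparisons, and the random block kept all. For stage the fixed block could not be fitted, because numbers lie within stages, and no number block was run for the reference. The numbers lean to pairing without meeting the criterion that every pair of 1 number correlates at over 0.1. The 7 such pairs correlated at -0.168 to 0.362 across genes (median 0.167) and 26 other pairs at -0.513 to 0.413 (median -0.00700). The random number block of the region comparisons had a consensus correlation of 0.270, and 1 of 8 arrays correlated best with its own number. Arrays of 1 number also shared Theiler stage and the pattern of Xist, Eif2s3y and Uty given below. These correlations therefore cannot tell a shared embryo from shared stage and sex, and the main fits take the arrays as unpaired.

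With title style as a fixed block the sign turned for Hand2 (0.40, urethra against urogenital sinus) and Gas1 (-0.33, bladder against urethra). Among lists that passed the camera test in the main fit, the posterior Hox median turned. It was 0.047 for bladder against urogenital sinus with median centring. Medians of lists that had not passed it turned in further pairs of a list and a setting, with single left-out arrays not counted. Such pairs numbered 16 for bladder against urogenital sinus, 26 for urethra against urogenital sinus and 24 for bladder against urethra. For the reference there were 8 and for stage 36. All 41 named genes called for bladder against urogenital sinus kept their sign in every setting run, as did 57 of 58 for bladder against urethra, 2 of 2 for urethra against urogenital sinus and 82 of 82 for the reference; 7, 3, 0 and 51 kept their call in every setting. Those kept for bladder against urogenital sinus were Actg2, Aoc3, Cldn11, Myom1, Nr4a3, Rbfox1 and Serpinb1a, and for bladder against urethra Cbr2, Nr4a3 and Sall1. Signal near the floor limits what low genes can show.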

Other observations

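Xist and 2 of the 3 Y-linked genes measured divided the region arrays by replicate number. Xist, the RNA expressed from the inactive X chromosome of females, lay between 14.82 and 16.32 on the arrays of replicates 1, 2 and 7, where the Y-linked Eif2s3y was at the floor of 5.65. On the arrays of replicates 6 and 8, Xist lay between 7.60 and 9.95 and Eif2s3y between 11.25 and 12.22. The Y-linked Uty was 5.65 to 6.61 on the former arrays and 8.66 to 10.06 on the latter. The Y-linked Kdm5d did not divide them: it was 6.24 to 7.93 on the former, 9.21 to 10.23 on replicate 6 and 5.70 on bladder replicate 8. The newborn reference, a pool of both sexes, had Xist at 14.83 to 15.23 and Eif2s3y at 9.35 to 10.61. Each number shared by several regions thus carried 1 pattern of Xist, Eif2s3y and Uty, and the labels give the sex of the embryos as unknown. The patterns were not balanced over the regions: bladder replicates 6 and 8, urogenital sinus replicate 6 and urethra replicate 6 had low Xist and high Eif2s3y. No fit had sex as a term, so the main fits did not separate it from region. A fixed block for title number does hold the pattern constant, because each number carried 1 pattern. Under that block 22 of the 41 named genes called stayed called for bladder against urogenital sinus. The same held for 0 of 2 for urethra against urogenital sinus and 18 of 58 for bladder against urethra. The block also takes up stage, so the lost calls cannot be traced to sex.

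Whether the difference between stages varied with region was tested with an interaction of stage and region. By limma 0 of 15019 genes passed, with a smallest adjusted p of 1.00, and 223 had an unadjusted p under 0.05 against 751 by chance. That fit has 4 residual degrees of freedom.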
